A study of Gallus gallus with 6 samples.

How the data were processed

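Leg muscle of Daheng broiler (DH) and Tibetan chicken (TC) embryos at E10, E14 and E18 was measured by droplet single-cell RNA sequencing, with 1 library per breed and stage and 6 in all. Per the labels' protocols, the tissue was digested with collagenase I for 30 min, passed through a 40 μm strainer and made into libraries with the 10x Genomics Single Cell 3′ kit v2, sequenced on a NextSeq 500. The kit version is that of the labels and was not checked against a list of barcodes. The design text says that each library pooled several male embryos. Breed and stage were taken from the sample titles. Nothing in the labels gives a library or sequencing batch.

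The deposited values are raw counts, that is, whole-number UMI counts per gene and barcode in a sparse matrix for each library, which the authors made with Cell Ranger 3.1.0 per the file headers. The submitters' processing notes also name STAR, Seurat 3.1.1 and the genome build GRCg6a. Each matrix listed 24167 features and only barcodes with at least 500 UMIs. No coordinates are printed, because the reference table at hand is of another assembly (GRCg7b) and was used only for names, for RNA biotype and for which genes lie on the chromosome of HINTW or of DMRT1. Of the 24167 features, 18484 symbols matched it. The files pair each feature with its symbol, which is used here as the identifier. Cell Ranger counts only reads that map to 1 gene, so counts of near-identical copies such as HINTW or myosin heavy chain genes are too low.

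Cells were kept with at least 500 genes and at most 10% mitochondrial UMIs. Doublet scores were computed per library with Scrublet, as implemented in scanpy 1.11.5, and the top-scoring barcodes were removed at 0.8% per 1000 barcodes, which took out 3333 barcodes. Of 71278 barcodes, 31339 (44.0%) were kept. The share kept was 46.0%, 33.2% and 44.3% in DH and 46.8%, 35.0% and 69.5% in TC, in order of stage. Before filtering, the median mitochondrial share was 8.82%, 11.7% and 8.93% in DH and 9.64%, 11.2% and 4.40% in TC. Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes were chosen across libraries, mitochondrial genes were left out of these, and 30 principal components of the unit-variance values gave 15 nearest neighbours per cell. Leiden clustering (leidenalg 0.10.2, resolution 1.0) ran on edges weighted by shared neighbours, without integration, and gave 47 clusters. A cluster was named from marker lists fixed before the data were examined, for the class with the highest mean fold of its 5 leading markers over the other clusters (pseudocount of 20 CPM). At least 3 markers had to be found in 10% of the cells and raised by 0.5 on the log2 scale, and its 10 leading genes could not hold more markers of another class than of its own. A cluster with a UMI ratio to its libraries' medians under 0.333 and no own marker among those 10 stayed unnamed. These limits of the naming were set after the data were seen. In this way 41 clusters were named, and the names are marker-based likenesses. Cells in the 6 unnamed clusters entered no class, and those whose best marker score was fibroblast are given as their own share. Cells of E10, E14 and E18 lay largely in different clusters, so named genes that differ between stages and are among the 10 leading genes of a cluster of the class tested are pointed out. The muscle lineage joins the clusters named myogenic progenitor, myoblast or myocyte, and muscle fibre.

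Raw counts of each class with at least 50 cells in every library were summed per library and tested with edgeR 4.0.16 (glmQLFit and glmQLFTest, TMM factors, filterByExpr on stage) in R 4.3.3, with breed and stage as additive terms and 2 residual degrees of freedom. Genes with a Benjamini-Hochberg adjusted p under 0.05 count as changed. The interaction of breed and stage serves as the error, so p-values measure the spread between these 6 pooled libraries and not between embryos. The standard error of a log2 fold change was taken as its size divided by the square root of F, and is not given where F is close to 0. A change is read as rise or fall relative to the scaling. The median log2 change of all tested genes lay within 0.1 of 0 in each comparison under each scaling tried. Shares of cells carry exact Clopper-Pearson intervals at 95% and differences of shares Newcombe intervals. Intervals cover counting error only, and a count of 0 allows 3 counts. Ratios with 1 to 3 counts in a library carry exact conditional binomial intervals. They rest on library sizes scaled by TMM factors. CPM values set beside those of other cell classes use unscaled totals, so the ratios do not follow from them.

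The 16 gene lists were fixed before the data were examined: contractile apparatus, myogenic regulators, cell cycle, extracellular matrix, tendon and cartilage, adipogenesis and lipid, glycolysis, oxidative phosphorylation, hypoxia response, IGF and insulin, TGF-beta and BMP, Wnt, Notch, dissociation stress, ribosomal proteins and mitochondrially encoded genes. They were tested with camera (limma 3.58.1) with a preset correlation of 0.01 and again with an estimated one, with Benjamini-Hochberg adjustment over the lists of a comparison. Camera was run for E18 against E10 and for TC against DH only, and with the estimated correlation no list passed in either. That form tests on the 2 residual degrees of freedom, so it has little power whatever the correlation. For Wnt by stage in muscle lineage the estimated correlation was −0.0182, below the preset one. Its unadjusted camera p still went from 0.000433 to 0.0546. A list that does not pass with an estimated correlation is therefore not shown to be unchanged. Named genes follow a rule fixed beforehand: the 12 largest rises and the 12 largest falls among changed genes with a mean of at least 20 CPM, a symbol and 1 direction in both breeds (stage) or at all 3 stages (breed), or, where no gene passed, the 5 genes with the lowest p; up to 4 members per list by p; and PAX7, MYF5, MYOD1, MYOG, MYF6, MSTN, IGF1 and IGF2. Of the genes the rule gives, those that best describe a comparison are printed. The result of 1 gene given by the rule is left out and not reported here. COL1A1 and COL4A1 as background genes, CNMD, ARIH1_1 and the genes of the glucocorticoid list were named outside that rule, after values were seen or for a test of their own.

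The tests were tried on simulated counts with the means and library sizes of these data, 100 genes changed by 2-fold and 100 by 4-fold. Of the genes changed 4-fold, 69% were recovered for E18 against E10 and 73% for TC against DH in muscle lineage, 74% and 80% in fibroblasts, and 34% and 63% in all cells. Of those changed 2-fold, 5% and 9%, 8% and 27%, and 2% and 9% were recovered. Of the genes called, 17 of 91 and 7 of 89 in muscle lineage, 7 of 89 and 9 of 116 in fibroblasts, and 2 of 38 and 13 of 85 in all cells were unchanged ones, a share above the nominal 0.05 in each. No simulation was repeated, so these shares carry counting error, and 2 of 38 lies close to the nominal share. The low recovery of 2-fold changes limits what a missing call says, and these false calls limit what a call says. Far fewer genes were changed in the simulation than the 3006 called for E18 against E10 in muscle lineage. Recovery and the share of false calls depend on that proportion, so these rates need not hold for the stage tests.

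The alternatives fixed beforehand were DESeq2 1.42.0, median-of-ratios (RLE) factors, no low-count filter, the other factor left out, each library left out, doublets kept, a looser cell filter (200 genes, 20% mitochondrial UMIs), resolution 2.0, components centred within each library, a floor of 50 CPM for correlations, and the estimated correlation for lists. Alternatives chosen after seeing the data were cells with a HINTW UMI left out, 3 abundant rRNA-like features left out, a widened fibroblast class and myogenic progenitors alone. Computation used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.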

Results

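Single-cell RNA sequencing was carried out on leg muscle of chicken embryos from the Daheng broiler (DH), a meat-type breed, and the Tibetan chicken (TC), a highland breed, at embryonic days 10, 14 and 18 (E10, E14 and E18). Each of the 6 libraries stands for 1 breed at 1 stage and was made from a pool of several embryos described as male. The files held 71278 cell barcodes. Total UMI counts were 102320737 in DH E10, 53415217 in DH E14, 55303761 in DH E18, 103320415 in TC E10, 87663471 in TC E14 and 37602569 in TC E18. After filtering, 31339 cells remained, namely 6027, 3765 and 5039 in DH and 5942, 5336 and 5230 in TC, in order of stage, with median depths from 4899 UMIs per cell in DH E14 to 9637 in DH E10. There was 1 library per breed and stage, so a stage comparison had 1 library of each breed on either side, a breed comparison had 3 libraries per breed, and the spread in each test was the departure from a breed difference that is the same at all 3 stages.

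HINTW, a multicopy gene of the W chromosome that only female birds carry, was examined first as a check of the sex named in the labels. It was found in the library labelled DH E10, with 159068 UMIs, and in the library labelled TC E18, with 15393 UMIs. DH E14 held 10 UMIs of it and DH E18, TC E10 and TC E14 held 0, for which a count of 0 allows up to 3. Of the kept cells, 83.6% carried a HINTW UMI in DH E10 and 41.7% in TC E18. These 2 libraries therefore went against the label as to sex, and the numbers of changed genes in each comparison below were also computed with the cells carrying a HINTW UMI left out. DH E10 then held 332 muscle lineage cells and 223 fibroblasts. For E18 against E10, E14 against E10 and E18 against E14, 2944, 734 and 1340 genes changed in muscle lineage, against 3006, 580 and 1095 with all cells. In fibroblasts 3460, 1335 and 930 changed, against 3764, 1370 and 779.

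The first question was how the cell make-up of the leg muscle differed with stage and breed. The muscle lineage, which joins PAX7-positive progenitors, MYOG-expressing myoblasts or myocytes and fibres with sarcomere transcripts, made up 33.3%, 60.8% and 34.5% of DH cells at E10, E14 and E18, and 54.3%, 50.1% and 12.3% of TC cells. Fibre-like cells were most frequent at E14, with 33.3% in DH and 15.3% in TC, against 4.60% and 6.93% at E10 and 1.13% and 1.66% at E18. Myoblast-like cells made up 14.6%, 15.7% and 4.94% of DH cells and 36.5%, 24.3% and 3.06% of TC cells. Progenitor-like cells made up 42.3% of the muscle lineage in DH E10 and 82.4% in DH E18, and 20.1% and 61.5% in TC. Tendon-like cells, led by FMOD, TNMD and COMP, were 19.5% of DH E18 and 19.2% of TC E18 cells, and 1 cell in each E10 library. In DH E10, however, TNMD stood at 248 CPM in fibroblasts and 8.43 CPM in erythroid cells, so it was present outside the tendon-like class. Cluster 28, named cartilage or perichondrium, and the unnamed cluster 4, both held largely by E10 cells, each had 1 tendon marker among their leading genes.

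Fibroblast-like cells made up 26.2%, 29.0% and 27.0% of DH cells and 20.5%, 36.9% and 54.8% of TC cells, in order of stage. A further 24.9% of DH E10 and 14.4% of TC E10 cells lay in unnamed clusters whose best marker score was fibroblast, against 0.179% and 2.96% at E18. Schwann-like cells were 11.6% of DH E18 and 2.24% of TC E18. The change of the muscle lineage share from E10 to E18 was 1.23 percentage points in DH (95% interval −0.539 to 3.003) and −42.1 points in TC (−43.6 to −40.5). In DH it was 2.32 with doublets kept, 9.20 with the looser cell filter and 8.26 with library-centred components, whose intervals lie above 0. At resolution 2.0 it was 1.74, with an interval that includes 0. The share in TC minus that in DH was 21.0 points at E10, −10.8 at E14 (−2.69 with the looser filter and −5.34 with library-centred components) and −22.3 at E18. These shares had no replicate and no test, the intervals (Newcombe) cover counting error only, and the tissue had passed a 40 μm strainer, which can hold back long fibres. The cell filter also acted unevenly on the libraries. With the looser filter muscle lineage cells went from 1740 to 3517 in DH E18, but only from 642 to 756 in TC E18. Different clusters held a class at different stages: muscle lineage cells of E10 lay mostly in clusters 0, 12, 19, 27, 13, 16 and 35, those of E14 in clusters 6, 10, 15, 26, 29, 16, 13 and 24, and those of E18 in clusters 1, 6 and 41, while fibroblasts of E10 lay in clusters 2, 14 and 32, those of E14 in 7 in DH (815 of 1091) and 5 in TC (1291 of 1970), and those of E18 in 8 and 9 in DH and 3, 21 and 8 in TC.

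**Figure D1:**
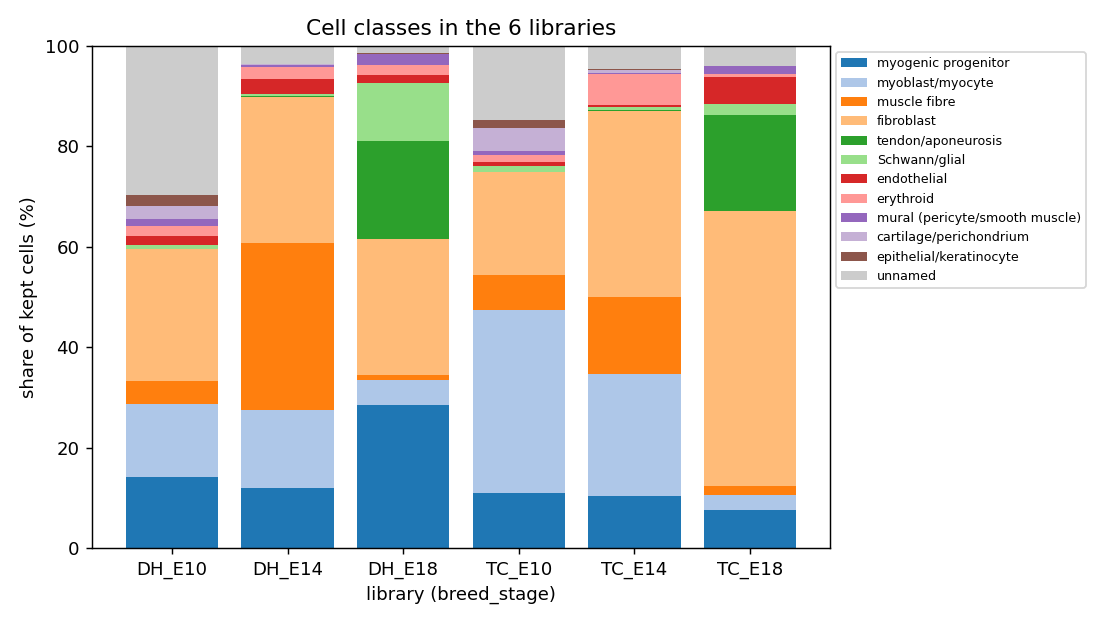
Share of kept cells (%, vertical axis) in each cell class, stacked, for the 6 libraries (horizontal axis, breed and stage), with 1 library per bar. The muscle lineage (the 3 lowest segments) was 60.8% of DH E14 and 12.3% of TC E18, and tendon-like cells were 19.5% and 19.2% of the E18 libraries.

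The next question was how muscle lineage cells changed with embryonic age. From E10 to E18, 36 of 45 extracellular matrix genes rose in the muscle lineage and 30 of 40 cell cycle genes fell. KLF9, a zinc-finger transcription factor, rose by 6.83 ± 0.48 on the log2 scale (SE), CEBPD by 7.69 ± 0.46, COL6A1, a chain of type VI collagen, by 7.17 ± 0.56 and the collagen-processing protease ADAMTS2 by 7.71 ± 0.60. UCHL1, a ubiquitin hydrolase, fell by 4.74 ± 0.32, the transcriptional cofactor EYA2 fell by 3.85 ± 0.28 and the sialyltransferase ST6GAL2 fell by 5.03 ± 0.32. COL6A1 stood at 486 CPM in muscle lineage and 73.3 CPM in erythroid cells of DH E18, but at 852 and 1240 CPM in TC E18. The other rises named here were not set against the erythroid level, so free RNA of other cell classes was not checked for them. The largest adjusted p of these 7 genes was 0.000598 (edgeR quasi-likelihood test, Benjamini-Hochberg, 6 libraries). In all, 3006 of 14308 genes changed, 1729 upward and 1277 downward.

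Among regulators of myogenesis, MYF5, which marks committed progenitors, rose by 3.40 ± 0.26 and PAX7, the satellite cell factor, by 1.95 ± 0.41 (edgeR adjusted p = 0.0176), while progenitors rose from 42.3% to 82.4% of the lineage in DH and from 20.1% to 61.5% in TC. MYF6 rose by 2.04 ± 0.43. In progenitors alone, MYF5 rose by 2.66 ± 0.24, PAX7 by 1.17 ± 0.29 and MYF6 by 1.90 ± 0.33. MYOD1 (−0.58 ± 0.25) and MYOG (−0.47 ± 0.26), which drive differentiation, did not pass the test. IGF2 rose by 3.74 ± 0.44. MSTN, which encodes the growth inhibitor myostatin, went from 465 and 515 UMIs at E10 in DH and TC to 1 and 1 at E18. On TMM-scaled library sizes this is 141 times lower in DH (95% counting interval 25.2 to 5582) and 47.7 times lower in TC (8.52 to 1887). MSTN is given for the whole lineage only. Over these stages myoblast-like cells went from 43.9% to 14.3% of the lineage in DH and from 67.1% to 24.9% in TC. Of 22 myogenic regulators tested, 6 rose and 2 fell, MET and BHLHE41 among the first and EYA1 among the second, and in progenitors alone 11 rose.

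Of 45 extracellular matrix genes, 36 rose from E10 to E18 and 2 fell (36 and 2 adjusted over the list alone). The basement membrane laminins LAMA2, LAMB1 and LAMC1 rose by 3.98 ± 0.28, 3.86 ± 0.28 and 3.86 ± 0.28, and the proteoglycan VCAN fell by 3.65 ± 0.27. Of 20 tendon and cartilage genes 9 rose and 0 fell, among them FMOD (7.99 ± 0.71) and CHAD. CHAD went from 2 and 1 UMIs at E10 to 858 and 211 at E18. On TMM-scaled library sizes this is a ratio of 1413 in DH (390 to 11680) and 2285 in TC (406 to 90670). At E18, FMOD in muscle lineage was below the erythroid level in both breeds (21.8 and 40.3 CPM in DH, 109 and 226 CPM in TC), and CHAD was near it in TC (60.1 and 52.2 CPM) and at 86.3 CPM in DH, with 0 UMIs in erythroid cells. At E18, COL1A1, a fibroblast and tendon transcript, stood at 1973 CPM in muscle lineage and 1983 CPM in erythroid cells of DH, and at 8642 and 34328 CPM in TC, whereas COL4A1 stood at 4200 CPM in muscle lineage and 143 CPM in erythroid cells of DH, and at 4819 and 238 CPM in TC. Of the 9 risen basement membrane genes all 9 stood over 2 times above the erythroid level in both E18 libraries, and of the 36 other risen genes of these lists 17 did in DH and 1 in TC (CNMD). The TC level rests on 34 erythroid cells, 19 of them in cluster 46, which had COL6A2 among its 10 leading genes. Both lists passed camera with a preset correlation of 0.01 and not with an estimated one (adjusted p = 0.328 with an estimated correlation for extracellular matrix and adjusted p = 0.320 for tendon and cartilage).

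Of 40 cell cycle genes, 30 fell and 0 rose (34 and 0 adjusted over the list alone). TOP2A, the topoisomerase of dividing cells, fell by 2.27 ± 0.32, the kinetochore gene CENPF fell by 2.03 ± 0.26 and TYMS fell by 2.39 ± 0.31 (adjusted p = 0.328 for the list with an estimated correlation). Of 29 hypoxia response genes 12 rose and 1 fell, with ADM at 3.91 ± 0.34 and BNIP3 at 2.89 ± 0.28 (adjusted p = 0.328 with an estimated correlation). Of 31 dissociation stress genes, which immediate handling of tissue can induce, 19 rose and 3 fell, with ATF3 at 3.50 ± 0.28 and EGR1 at 3.21 ± 0.30 (adjusted p = 0.320 with an estimated correlation). Their summed share of the muscle lineage UMIs was 1.18%, 3.43% and 3.43% in DH and 0.802%, 1.76% and 2.70% in TC, in order of stage.

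Among the signalling lists, 7 genes rose and 2 fell of 27 for IGF and insulin (IGFBP7 3.12 ± 0.24), 11 rose and 3 fell of 36 for TGF-beta and BMP (INHBA 5.80 ± 0.35, BMP4 5.57 ± 0.31), and 10 rose and 2 fell of 37 for Wnt (DKK3 4.03 ± 0.26, WNT4 3.46 ± 0.28). With an estimated correlation the adjusted p was 0.320 for each of these 3 lists. Notch had 6 rises and 2 falls among 19 genes (HES4 3.38 ± 0.25; adjusted p = 0.365 with an estimated correlation). Of 27 adipogenesis and lipid genes 8 rose and 1 fell, with LPL at 3.50 ± 0.25 (adjusted p = 0.425 with an estimated correlation). The genes named from these lists were not set against the erythroid level. Of 44 contractile genes 11 rose and 3 fell, of 23 glycolysis genes 2 rose and 3 fell, and none of 51 oxidative phosphorylation, 75 ribosomal protein or 15 mitochondrially encoded genes passed the edgeR gene test. These last 5 lists did not pass camera, and neither did the myogenic regulators. In progenitors alone 24 of 51 oxidative phosphorylation genes fell and 0 rose (adjusted p = 0.312 for the list by camera with an estimated correlation). There 5 of 15 mitochondrially encoded genes fell and 0 rose, and 8 of 21 glycolysis genes fell and 1 rose. Of 74 ribosomal protein genes 8 rose and 3 fell in progenitors, and of 36 contractile genes 11 rose and 7 fell. LAMA2, PAX7, CENPF, TOP2A and VCAN were also among the 10 leading genes of a cluster of this lineage. Without DH E10 the number of changed genes was 1433 and without DH E18 it was 1682.

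From E10 to E14, 10 of 44 contractile genes rose in the muscle lineage and 3 fell, in a count made after single genes had been seen. LMOD2, an actin filament nucleator of the sarcomere, rose by 5.77 ± 0.91, CMYA5 by 5.96 ± 0.65, TCAP, which anchors titin, by 5.46 ± 0.76 and the slow myosin gene MYH7B by 5.09 ± 0.65, while CKB fell by 3.90 ± 0.41 and UCHL1 fell by 2.90 ± 0.28. MYF5 (0.92 ± 0.24), PAX7 (0.06 ± 0.41), MYOD1 (0.28 ± 0.25) and MYOG (−0.67 ± 0.25) did not pass. Of 14308 genes 580 changed, 470 upward and 110 downward (edgeR, with adjusted p = 0.0127 for CMYA5 and 0.0249 for LMOD2). LMOD2, CMYA5, MYH7B and CKB were also among the 10 leading genes of clusters of this lineage. The fibre share of the lineage was 13.8% and 54.7% in DH at these stages and 12.8% and 30.7% in TC. The count was 326 without DH E10, 340 without DH E14, 976 without DH E18, 897 without TC E14 and 1174 without TC E18.

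From E14 to E18, 7 of 44 contractile genes fell and 1 rose, and 27 of 45 matrix genes rose and 1 fell, in the same kind of count. LMOD2 fell by 4.84 ± 0.89 and MYH7B fell by 3.60 ± 0.61, and of the laminins LAMC1 rose by 2.77 ± 0.26. MYF5 rose by 2.48 ± 0.25 and PAX7 by 1.89 ± 0.41, INHBA by 4.36 ± 0.33 and the glucocorticoid receptor co-chaperone gene FKBP5 by 5.02 ± 0.30. CENPF fell by 1.46 ± 0.25 and AURKA fell by 1.96 ± 0.36. In all 1095 genes changed, 727 upward and 368 downward (edgeR, with adjusted p = 0.0388 for PAX7 and 0.00258 for FKBP5). LMOD2, MYH7B, PAX7 and CENPF were also among the 10 leading genes of clusters of this lineage. The fibre share of the lineage was then 3.28% in DH E18 and 13.6% in TC E18. The count was 665 without DH E14, 444 without DH E18 and 1770 without TC E10.

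**Figure D2:**
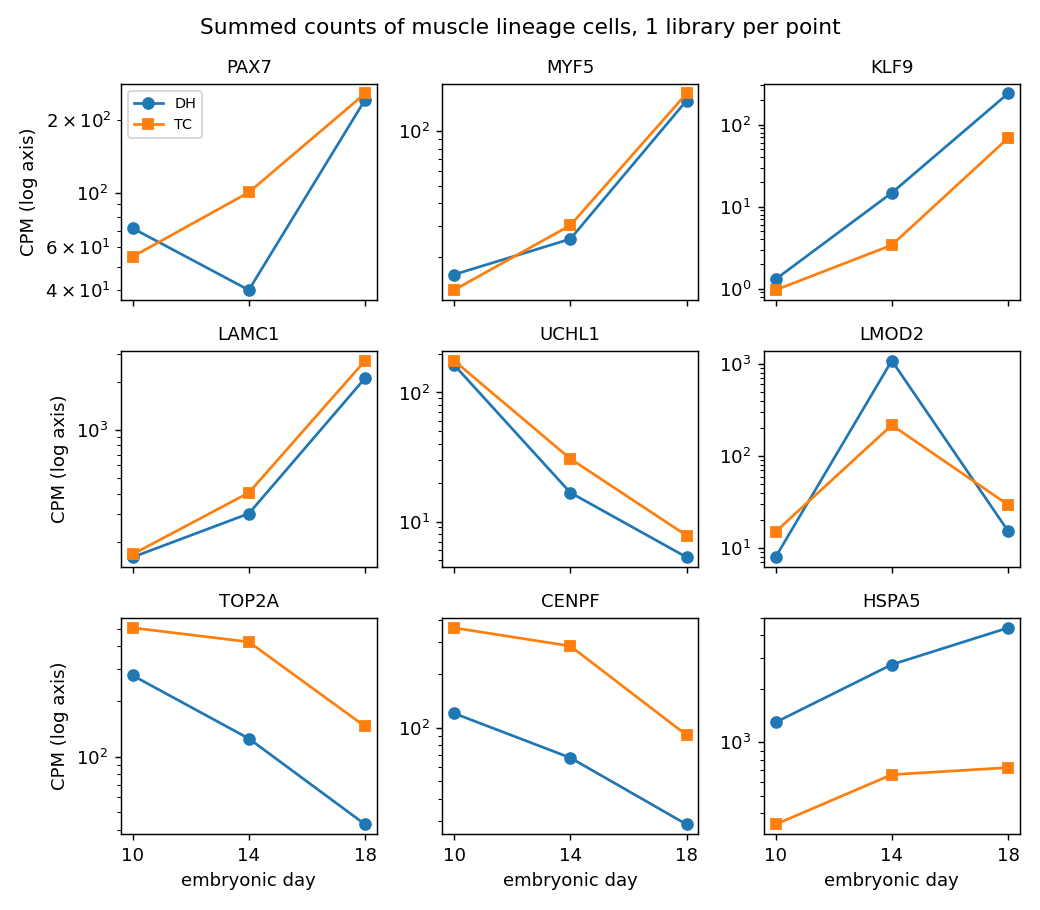
CPM of 9 genes (vertical axes, log scale) in the summed counts of muscle lineage cells against embryonic day (horizontal axis), with 1 library per point, DH as circles and TC as squares. KLF9, LAMC1 and MYF5 were highest at E18, LMOD2 at E14, UCHL1 at E10, and HSPA5 lay lower in TC than in DH at all 3 stages.

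Fibroblasts were compared across the same stages. From E10 to E18, 38 of 45 matrix genes rose and 37 of 40 cell cycle genes fell, the latter depending on which cells the class holds. PCOLCE2, a collagen maturation factor, rose by 8.09 ± 0.47, KLF9 by 7.20 ± 0.37 and the circadian repressor BHLHE40 by 6.97 ± 0.42. MGP, which inhibits calcification, went from 8 and 3 UMIs at E10 in DH and TC to 8292 and 6535 at E18. On TMM-scaled library sizes this was a ratio of 3571 in DH (95% counting interval 1811 to 8273) and 2176 in TC (744 to 10560). The CPM values that follow carry no TMM factors. At E18 MGP stood at 957 CPM in fibroblasts and 114 CPM in erythroid cells of DH, but at 368 and 232 CPM in TC, where muscle lineage held 2898 CPM, so free RNA can enter the TC value. NES fell by 4.96 ± 0.42, UCHL1 fell by 4.70 ± 0.32 and the axon guidance receptor gene ROBO2 fell by 5.70 ± 0.32. In all 3764 of 14157 genes changed, 2024 upward and 1740 downward (edgeR, with adjusted p of at most 0.001, that of NES, for these genes).

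Of 45 extracellular matrix genes 38 rose in fibroblasts and 0 fell (41 and 0 adjusted over the list alone), with LAMA2 at 4.76 ± 0.26 and COL15A1 at 4.70 ± 0.26. Of 40 cell cycle genes 37 fell and 0 rose, with CENPF at −3.32 ± 0.22 and CDC20 at −3.69 ± 0.27. Clusters 11 and 36, whose best marker score was fibroblast and whose leading genes include BUB1B, stayed unnamed and lie outside this class, with 446 DH E10, 276 TC E10 and 150 TC E18 cells. With such clusters added to the class 15 of the 40 genes fell, and with doublets kept 7 did, CENPF then being at −0.52 and CDC20 at −0.47 and neither passing. Of 38 Wnt genes 13 fell and 7 rose. Cluster 2 held 973 of 1582 DH E10 and 709 of 1218 TC E10 fibroblasts, and 0 cells of either E18 library. Its 10 leading genes include SFRP2, WNT11 and DKK2 of this list, so the Wnt count also compares different clusters. DKK1, a secreted Wnt antagonist, went from 1021 and 681 UMIs to 2 and 3. On TMM-scaled library sizes this is 148 times lower in DH (40.9 to 1224) and 227 times lower in TC (77.5 to 1106). TCF7 fell by 4.97 ± 0.31. Of 28 hypoxia genes 14 rose and 1 fell (EGLN3 3.99 ± 0.22), of 37 TGF-beta and BMP genes 11 rose and 3 fell (FSTL3 4.79 ± 0.32), and of 22 tendon and cartilage genes 12 rose and 4 fell. FMOD rose by 6.21 ± 0.42, but at E18 it was under 2 times the erythroid level in both breeds (77.6 and 40.3 CPM in DH, 300.1 and 226 CPM in TC), against 4202 and 5215 CPM in tendon-like cells. With an estimated correlation each of these 6 lists had an adjusted p of 0.252.

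Of 31 dissociation stress genes 23 rose and 2 fell in fibroblasts (SOCS3 4.03 ± 0.33). Of 28 adipogenesis and lipid genes 10 rose and 3 fell (FABP5 3.79 ± 0.27), and of 28 IGF and insulin genes 9 rose and 2 fell (IGFBP7 4.73 ± 0.50). With an estimated correlation the adjusted p was 0.301 for each of these 3 lists. IGF2 rose by 1.69 ± 0.37 and IGF1 (−0.04 ± 0.26) did not pass the edgeR test (adjusted p = 0.927). ROBO2 was also among the 10 leading genes of a fibroblast cluster held mostly by E10 cells. Without DH E10 the number of changed genes was 1676 and without TC E10 it was 1858.

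Between E10 and E14, DLK1 (4.90 ± 0.31), COL15A1 (3.57 ± 0.25), the growth factor gene IGF1 (1.70 ± 0.25) and BMP4 (2.49 ± 0.27) rose in fibroblasts, and TCF7 fell by 4.94 ± 0.31, CENPF fell by 2.44 ± 0.21 (0.12 at clustering resolution 2.0, −0.72 in a widened fibroblast class) and IGF2 fell by 1.57 ± 0.37. In all 1370 genes changed, 716 upward and 654 downward. Between E14 and E18, 779 genes changed, 560 upward and 219 downward. FKBP5 rose by 4.92 ± 0.34, LAMA2 by 3.82 ± 0.25 and IGF2 by 3.27 ± 0.40, IGF1 fell by 1.74 ± 0.26, and the cholesterol synthesis genes CYP51A1, SQLE and HMGCS1 fell by 3.75 ± 0.29, 3.50 ± 0.34 and 2.71 ± 0.22. The largest edgeR adjusted p of the genes named here was 0.0466 for IGF2 between E10 and E14. The first count was 190 without DH E10, 256 without DH E14, 485 without TC E10, 477 without TC E14, 4161 without DH E18 and 4164 without TC E18, and the second was 235 without DH E14, 194 without TC E14, 2492 without DH E18 and 1964 without TC E18.

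Summed over every kept cell, which mixes expression with cell make-up, 2581 of 16572 genes changed from E10 to E18, 1523 upward and 1058 downward. Of 23 tendon and cartilage genes 12 rose and 2 fell (adjusted p = 0.416 for the list with an estimated correlation), with FMOD at 8.68 ± 0.40, COMP at 7.05 ± 0.61 and TNMD at 4.19 ± 0.34, beside a tendon-like share of 19.5% and 19.2% at E18. APOA1, an apolipoprotein, rose by 8.49 ± 0.52. MYOG fell by 1.55 ± 0.30, TNNT2 fell by 3.17 ± 0.47 and CRABP1 fell by 4.30 ± 0.28, and MYF5 rose by 2.31 ± 0.40 (edgeR, with a largest adjusted p of 0.0279 for MYOG). Apart from MYF5, each of these genes was also among the 10 leading genes of a cluster. The count was 1011 without DH E10, 1678 without DH E14, 536 without TC E10 and 1549 without TC E14.

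The breed comparison asked how TC differed from DH over the 3 stages. In muscle lineage cells, genes higher in TC included 5 of 40 cell cycle genes, and genes lower in TC included 3 of 31 stress genes. CENPF was higher in TC by 1.78 ± 0.21, DLGAP5 by 1.76 ± 0.22, the spindle checkpoint gene BUB1B by 1.64 ± 0.20 and CDC20 by 1.63 ± 0.25. The endoplasmic reticulum chaperone HSPA5 was lower in TC, at −2.19 ± 0.23, as were the small heat shock gene HSPB9 (−2.51 ± 0.21), the transcription factors NFATC1 (−2.52 ± 0.26) and MYC (−2.06 ± 0.26), and the hepatocyte growth factor receptor gene MET (−1.99 ± 0.32). Each named gene had its direction at all 3 stages. In all 131 of 14308 genes differed, 35 higher and 96 lower in TC (edgeR, adjusted p from 0.0357 for HSPB9 to 0.0492 for MET), and 4063 had an unadjusted p under 0.05.

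Of 40 cell cycle genes 5 were higher in TC muscle lineage and 0 lower (29 and 0 adjusted over the list alone), with a median log2 difference of 1.03, and adjusted p = 0.496 with an estimated correlation. In progenitors alone 14 of 40 cell cycle genes were higher in TC and 0 lower (24 and 0 adjusted over the list alone), with a median of 0.939. Myoblast-like cells were 67.1% of the lineage in TC E10 and 43.9% in DH E10, 48.4% and 25.8% at E14, and 24.9% and 14.3% at E18. Of 31 dissociation stress genes 3 were lower and 0 higher (14 and 1 adjusted over the list alone), namely HSPA5, HSPA2 (−1.86 ± 0.22) and FOSL2 (−1.69 ± 0.24), with adjusted p = 0.496 for the list with an estimated correlation. Of 51 oxidative phosphorylation genes 0 passed over all genes and 34 were higher adjusted over the list alone, such as NDUFA8 (1.01 ± 0.21) and UQCRFS1 (0.92 ± 0.20). In progenitors alone 0 passed by either adjustment, with a median of 0.404. In the whole lineage this list had adjusted p = 0.496 with an estimated correlation. Of 27 IGF and insulin genes 2 were lower, the insulin receptor substrates IRS2 (−2.04 ± 0.22) and IRS4 (−1.53 ± 0.19), and of 36 TGF-beta and BMP genes 1 was lower, BMP4 (−1.56 ± 0.23), both lists having an adjusted p of 0.496 with an estimated correlation.

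Of 27 adipogenesis and lipid genes KLF5 (−2.15 ± 0.24) and CPT1A (−1.74 ± 0.26) were lower in TC muscle lineage (adjusted p = 0.573 for the list with an estimated correlation). SLC2A1, the basal glucose transporter gene, was lower (−1.69 ± 0.24) and was the 1 member to pass in both the hypoxia list (29 genes, adjusted p = 0.638 with an estimated correlation) and the glycolysis list (23 genes). HES4 (−1.55 ± 0.19) was the 1 Notch gene of 19 to pass, and MET the 1 myogenic regulator of 22. None of 44 contractile, 45 matrix, 20 tendon and cartilage, 37 Wnt, 75 ribosomal protein or 15 mitochondrially encoded genes passed, and of these lists the ribosomal proteins passed camera with the preset correlation (adjusted p = 0.904 with an estimated correlation). MYOG (1.15 ± 0.21), MYOD1 (0.87 ± 0.20) and PAX7 (0.33 ± 0.33) did not pass (edgeR adjusted p = 0.0529, 0.0632 and 0.549). CENPF and CDC20 were also among the 10 leading genes of a cluster of the lineage. The count of 131 was 24 without DH E18, 10 without TC E14, 552 without DH E10 and 830 without TC E10, 451 without the cells carrying HINTW, 42 with RLE factors, 0 with library-centred components and 0 with stage left out of the model. The balance of directions also moved, with 7 higher and 35 lower in TC with RLE factors, 833 and 931 of 1764 with DESeq2, 807 and 863 of 1670 without the filter, and 584 and 518 of 1102 with the looser cell filter.

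In fibroblasts, 16 of 31 dissociation stress genes, heat shock genes among them, were lower in TC. HSPH1, a co-chaperone of HSP70, was lower at −2.92 ± 0.53, HSPB9 at −2.69 ± 0.31, HSP90AA1 at −1.83 ± 0.28, HSPA8 at −1.90 ± 0.28 and NFATC1 at −2.51 ± 0.19. PI16, a marker of adventitial fibroblasts and of a cluster held mostly by TC E18, was higher in TC by 2.41 ± 0.48, THY1 by 1.30 ± 0.24 and FGF10 by 1.30 ± 0.19. In all 864 of 14157 genes differed, 187 higher and 677 lower in TC (edgeR, adjusted p from 0.0157 for NFATC1 to 0.0416 for PI16), and 4222 had an unadjusted p under 0.05.

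Of 31 dissociation stress genes 16 were lower in TC fibroblasts and 0 higher (25 and 1 adjusted over the list alone), with a median log2 difference of −1.17 and adjusted p = 0.494 for the list with an estimated correlation. The list took 2.25%, 6.61% and 5.45% of fibroblast UMIs in DH and 1.15%, 2.34% and 1.97% in TC, in order of stage. Over all classes with at least 50 cells in both breeds at a stage, fibroblasts and muscle lineage included, 15 of 16 pairs of class and stage had a median log2 ratio below that of all genes. The mural cells of E18 were at 0.254, the Schwann-like cells of E18 were at −0.047, with 14 of 28 genes lower and a summed share of 2.13% in TC against 1.77% in DH, and the lowest value was −1.41 in erythroid cells of E10. Features matching ribosomal RNA and 1 further abundant feature, ARIH1_1, together took 9.004%, 13.03% and 15.9% of UMIs in DH and 16.8%, 21.7% and 21.5% in TC.

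**Figure D3:**
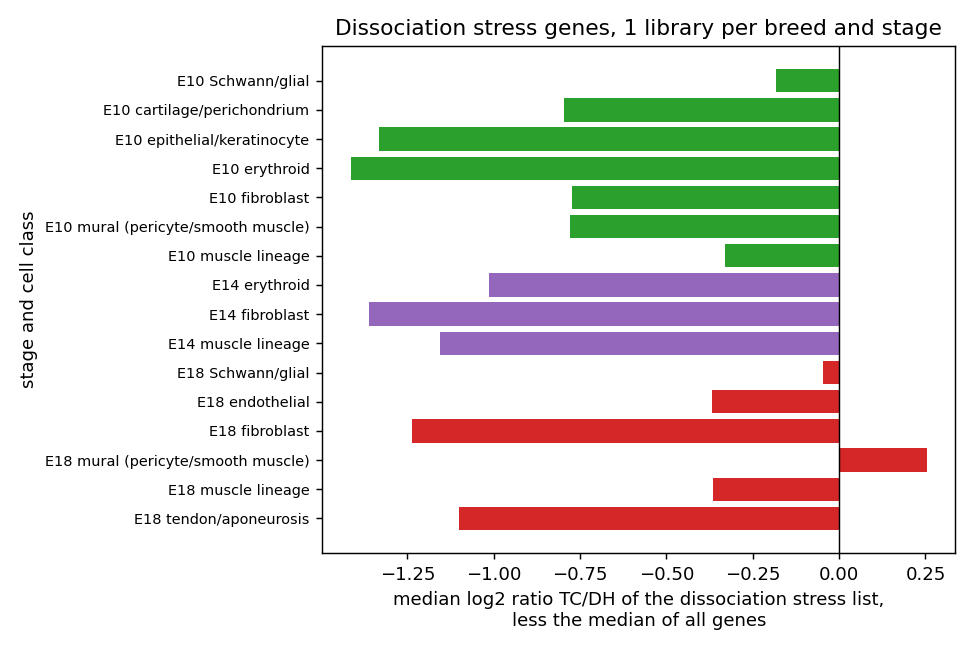
Median log2 ratio of TC to DH over the dissociation stress genes, less the median of all genes (horizontal axis), for each cell class and stage with at least 50 cells in both breeds (vertical axis), with 1 library per breed and stage and colours marking the stage. Of the 16 bars 15 lie below 0 and the lowest is −1.41 in E10 erythroid cells.

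Of 28 hypoxia genes 6 were lower in TC fibroblasts and 0 higher, among them PFKFB3 (−1.77 ± 0.16), EGLN3 (−1.09 ± 0.16) and SLC2A1 (−1.81 ± 0.29), and of 28 adipogenesis and lipid genes 4 were lower, among them PNPLA2 (−1.64 ± 0.21) and CEBPB (−1.60 ± 0.17). Both lists had an adjusted p of 0.494 with an estimated correlation. Of 51 oxidative phosphorylation genes SDHB (0.76 ± 0.15) and NDUFA1 (0.84 ± 0.18) were higher (adjusted p = 0.484 for the list with an estimated correlation). Of 45 matrix genes THBS1, which is among the leading genes of cluster 7, was lower (−2.08 ± 0.21) and 0 were higher, although the list passed camera upward with the preset correlation (adjusted p = 0.494 with an estimated correlation). Of 28 IGF and insulin genes 3 were lower, IRS2 (−1.77 ± 0.22), FOXO3 (−2.09 ± 0.33) and IRS4 (−1.16 ± 0.20). No cell cycle gene of 40 and no myogenic regulator of 19 passed. The unnamed clusters 11 and 36, with BUB1B among their leading genes, lie outside this class, so this cell cycle count leaves their cells out. In order of stage, cluster 11 held 446, 107 and 2 cells in DH and 276, 220 and 5 in TC. Cluster 36 held 0, 1 and 7 in DH and 0, 5 and 150 in TC. Most E14 fibroblasts lay in cluster 7 in DH and in cluster 5 in TC. Clusters 3 and 21 held 1502 and 619 TC E18 cells, against 50 and 22 of DH E18. The numbers of genes that differed between breeds therefore also compare different clusters at E14 and E18. The count of 864 was 10 without DH E14, 55 without TC E14, 2382 without DH E18, 2367 without TC E18, 1470 without the cells carrying HINTW, and 0 with stage left out of the model.

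Over all cells, no gene differed between the breeds past the edgeR threshold (0 of 16572), while 4365 genes had an unadjusted p under 0.05 and DESeq2 called 1907. The genes with the lowest p were PELI2 (−1.80 ± 0.16), PDP1 (−1.66 ± 0.16), NFATC1 (−2.10 ± 0.21), HSPB9 (−2.30 ± 0.23) and GCLC (−1.62 ± 0.17), each with an edgeR adjusted p of 0.0966 and lower in TC at all 3 stages. Without DH E18 the count was 286 and without TC E18 it was 422.

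Fold changes of single libraries were also compared across genes, which are not independent replicates. In the muscle lineage the log2 change from E10 to E18 in DH correlated with that in TC at r = 0.813 and rho = 0.742 over 5757 genes of at least 20 CPM, and in fibroblasts at r = 0.789 and rho = 0.727 over 5314 genes. The log2 ratio of TC to DH correlated between stages at r = 0.552 (E10 with E14), 0.479 (E10 with E18) and 0.458 (E14 with E18) in the muscle lineage, and at 0.721, 0.464 and 0.700 in fibroblasts, with rho from 0.505 to 0.728. Of the 5757 muscle lineage genes 3474 (60.3%) had 1 sign of the breed difference at all 3 stages, 2074 higher and 1400 lower in TC, and of the 5314 fibroblast genes 3284 (61.8%) did, 1825 higher and 1459 lower, where independent signs give 25%.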

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

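The tests of free RNA and of a wrong stage label for HINTW, the background and progenitor tests of matrix genes, and the counts of splits were chosen after the result was seen.

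The share of muscle lineage cells differed between breeds in opposite directions by stage, at 21.0 points (TC minus DH) at E10, −10.8 at E14 and −22.3 at E18, and its change from E10 to E18 was 1.23 points in DH and −42.1 in TC. With a looser cell filter and with library-centred components the change in DH was 9.20 and 8.26 points and the difference at E14 was −2.69 and −5.34. With 1 library each the difference was not tested.

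HINTW, which male birds lack, had 159068 UMIs in the library labelled DH E10, 15393 in TC E18 and 10 in DH E14. Free RNA spread over all droplets is argued against, because 16.4% of kept DH E10 cells held none where an even spread by depth would leave 1.33%, and 58.3% against 14.6% in TC E18. A wrong stage label is argued against, because 92.6% of DH E10 cells lay in clusters whose cells of the other breed came mostly from the labelled stage, as did 88.6% in TC E18. Female cells in these pools are consistent with the Z-linked genes, whose median log2 ratio in cells with HINTW over cells without it, relative to other genes, was −0.573 in DH E10 fibroblasts, −0.499 in DH E10 muscle lineage, −0.423 in TC E18 muscle lineage and −0.294 in TC E18 fibroblasts, against random ranges within 0.0653 of 0. A wrong breed label was not tested, nor was a biological explanation other than sex.

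Of 31 dissociation stress genes 16 were lower in TC in fibroblasts and 3 in muscle lineage. Female cells in DH E10 and TC E18 are argued against as the whole cause. Without the HINTW cells 21 stress genes were lower in fibroblasts, against 16 with them. Without the 3 abundant rRNA-like features 15 were lower, but TMM factors already limit the weight of a few dominant features. That count was therefore nearly fixed beforehand and cannot decide whether the greater share of these features plays a part. Handling of the libraries may account for the pattern: 15 of 16 pairs of class and stage were lower in TC, from −1.41 to 0.254, and a breed difference would give the same, so these cannot be told apart with each library being its own preparation. In myogenic progenitors alone the list's median was −0.17, with 4 genes lower and 2 higher. A biological difference between the breeds stays open and untested.

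In the muscle lineage 36 of 45 matrix genes and 9 of 20 tendon and cartilage genes rose from E10 to E18. A shift toward progenitors is argued against as the whole cause of the matrix rise, since 35 matrix genes rose in progenitors alone against 36 in the whole lineage. Free RNA of connective tissue cells is argued against for the basement membrane genes, all 9 of which stood over 2 times above the erythroid level in both E18 libraries. Of the 36 other risen genes 17 did in DH E18 and 1 in TC E18 (CNMD), where the erythroid level rests on 34 cells, so for these free RNA and an age-related rise cannot be told apart while the libraries differ.

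The breed counts were set against the 10 ways to split the 6 libraries into 3 and 3, of which 4 have 1 library of each stage on either side, as the real one does, and the other 6 gave 0 genes in each case. In muscle lineage 1 split, the real one, gave as many as 131 genes and the highest other gave 7. In fibroblasts 1 split, the real one, gave as many as 864 and the highest other gave 0. Over all cells, all 10 splits gave at least the 0 genes of the real one, and the highest other gave 5. With 10 splits no share under 0.05 can be had.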

How the results depend on the processing

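The alternatives without HINTW cells, without 3 features, with the widened fibroblast class and with progenitors alone were chosen after seeing the data. No paired analysis was possible because each breed and stage has 1 library, so there are no replicate numbers to pair. The breed test, with stage as a term, already compares the breeds within 3 stages. Of 548 single-gene results past the threshold, set against their alternatives in 8768 comparisons, 7879 kept direction and side of the threshold, 883 lost significance and 6 turned sign. Apart from the fixed regulators, these results were chosen for large changes or low p in the same data, so they are steadier than called genes at large. Of the 131 breed genes in muscle lineage, 129 were still called with DESeq2, 42 with RLE factors and 0 with library-centred components. The 2 residual degrees of freedom, and 19 fibroblasts in DH E14 under library-centred components, limit what can be tested: no fibroblast value was possible there, and leaving out DH E10 and TC E18 together leaves no residual degrees of freedom. Where 1 library is left out, the lone library left at its stage is assumed to vary like the others. The cause of the changes below was not tested.

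For muscle lineage, E18 against E10 gave 1092 genes with breed left out. E14 against E10 gave 1378 without the filter, 82 with breed left out, 1361 with DESeq2, 197 with centred components and 919 in progenitors alone. E18 against E14 gave 1897 without the filter, 305 with breed left out and 1830 with DESeq2. TC against DH gave 42 with RLE factors, 1670 without the filter, 0 with stage left out, 1764 with DESeq2, 425 with doublets kept, 1102 with the looser filter, 0 with centred components, 451 without HINTW cells and 996 in progenitors alone. For fibroblasts, E18 against E10 gave 1487 with breed left out. E14 against E10 gave 155 with breed left out, 778 with doublets kept and 715 in the widened class. E18 against E14 gave 1303 without the filter, 84 with breed left out, 1356 with DESeq2 and 1221 with the looser filter. TC against DH gave 1689 without the filter, 0 with stage left out, 1583 with DESeq2, 1330 with the looser filter, 540 at resolution 2.0 and 1470 without HINTW cells. Over all cells, E18 against E10 gave 1087 with breed left out and 4205 with DESeq2, and TC against DH gave 40 without the filter and 1907 with DESeq2. With each library left out in turn, counts ranged from 1433 to 3422 (muscle lineage, E18 against E10), 326 to 1174 (E14 against E10), 444 to 1770 (E18 against E14) and 10 to 830 (TC against DH); in fibroblasts from 1676 to 4879, 190 to 4164, 194 to 2492 and 10 to 2382; and over all cells from 536 to 3673 (E18 against E10) and 0 to 422 (TC against DH).

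The muscle lineage share change in TC was −38.6 points with doublets kept and −44.6 with centred components, and in DH it was 9.20 with the looser filter and 8.26 with centred components. TC minus DH was 28.0 at E10 with centred components, −2.69 and −5.34 at E14 with the looser filter and centred components, and −29.3 and −24.9 at E18. The breed ratios of E14 and E18 in fibroblasts correlated at 0.735 with a floor of 50 CPM. The list tests with an estimated correlation rest on 2 residual degrees of freedom, so a call lost there does not show that a list is unchanged. With an estimated correlation, list tests lost their call at adjusted p = 0.328 (muscle lineage by stage: cell cycle, extracellular matrix, hypoxia), 0.320 (tendon, IGF, TGF-beta, Wnt, stress), 0.425 (lipid) and 0.365 (Notch); at 0.496 (muscle lineage by breed: cell cycle, oxidative phosphorylation, IGF, TGF-beta, stress), 0.573 (lipid), 0.638 (hypoxia) and 0.904 (ribosomal); at 0.252 (fibroblasts by stage: cell cycle, extracellular matrix, tendon, hypoxia, TGF-beta, Wnt) and 0.301 (lipid, IGF, stress); and at 0.494 (fibroblasts by breed: extracellular matrix, lipid, hypoxia, stress) and 0.484 (oxidative phosphorylation). Sign changes were CENPE at 0.038 in muscle lineage (E18 against E14, centred components), CENPF at 0.12 and CENPE at 0.51 in fibroblasts (E14 against E10, resolution 2.0), and MKI67 at 0.54, CDC20 at 1.17 and CENPE at 1.23 in fibroblasts (E18 against E14, doublets kept).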

Other observations

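The test of glucocorticoid targets was planned before the values of its 11 genes were looked at. A first run had included 3 added genes, DDIT4, HSD11B2 and TAT, and DDIT4 had been seen to rise beforehand, so the run with the planned genes is the one read.

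Smaller cell classes also differed between libraries. Endothelial-like cells were 5.20% of TC E18, and erythroid cells were 6.28% of TC E14. The 2 ribosomal RNA features LOC112533599 and LOC112533601 took 4.09% and 2.41% of UMIs in DH E10 and 11.8% and 3.04% in TC E10.

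FKBP5, KLF9 and CEBPD, which the stress hormone corticosterone is known to induce, were among the largest rises to E18, and a hypothesis was drawn from them: that cells respond to glucocorticoid in the days before hatching. Of the 11 planned targets other than these, 8 could be tested, and from E10 to E18 7 of the 8 rose in muscle lineage and 6 of the 8 in fibroblasts. TSC22D3, a direct receptor target, rose by 3.04 ± 0.45 and 2.76 ± 0.36, GLUL by 3.44 ± 0.32 and 2.01 ± 0.24, and TXNIP by 2.52 ± 0.48 and 2.20 ± 0.52 (edgeR). The medians of the 8 genes were 2.39 and 2.11, each at the 99.99th percentile of 10000 random lists matched on expression. The random lists were drawn gene by gene, so the percentile ignores correlation between the genes and the spread between libraries. Both classes also come from the same libraries and are not independent of each other. With the 3 added genes 8 of 11 rose in muscle lineage and 7 of 11 in fibroblasts. The pattern is consistent with hormone-responsive transcription, but 19 and 23 of 31 dissociation stress genes rose over the same stages (adjusted p = 0.320 and 0.301 for the list with an estimated correlation), and no hormone was measured here, so other inducers of the same genes may also account for it.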
